A study of Mus musculus with 2 samples.

How the data were processed

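Chromatin of feeder-free E14 cells was cross-linked, fragmented and immunoprecipitated, per the labels' protocols. These name several antibodies without saying which was used for the arrays, and Tcf3 is taken here from the sample titles. Immunoprecipitate and input were amplified after linker ligation, labelled with Cy5 and Cy3 and hybridised to Agilent mouse promoter arrays. The authors read the spots with Agilent Feature Extraction 9.1.1.1, per the file headers. The deposited processed signals are an intensity per channel, background-subtracted, corrected for spatial and multiplicative trends and dye-normalized linearly by 1 factor per channel, per the file headers. Those factors were 3.58 (Cy3) and 3.18 (Cy5) on array 1 and 2.33 and 1.67 on array 2. Where a signal was not above background, the authors' software wrote a surrogate intensity, per the file headers. The deposited log10 ratio of Cy5 over Cy3 differs from the ratio of processed signals by 0.001 (log2) or more in 31736 spots of array 1 and 70071 of array 2, of which 0 were measured in both channels. The series value table, deposited by the authors without a stated scale, holds the error of that log10 ratio. Bound regions were called by the authors with a neighbourhood model after median normalization, per the labels, and their calls are not used here.

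Values were computed here as log2 of processed Cy5 over processed Cy3 and centred on the median of each array's non-control spots, leaving out spots marked as non-uniform (9 on array 1 and 18 on array 2). Each of the 474380 probes occurs as 1 spot. The scale of no enrichment was taken from the values below the median, as their median size converted to a normal SD, and was 0.72 on array 1 and 0.78 on array 2. A set was a probe with its nearest neighbour on each side within 1000 bp, of 2 to 3 probes. A probe was called when the upper-tail normal probability of its set mean was under 0.001 and either the probe itself was under 0.001 with a neighbour under 0.1, or 2 probes of the set were under 0.005. These probabilities describe the scatter on the array and served only as a calling rule. Called probes within 1000 bp formed 1 region, and a gene was called when the array annotation of a called probe named it. The highest set mean of a called gene can belong to a probe that was not called itself, as for Lef1. Because the arrays carry different probes, each was called alone.

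Gene names came from the array annotation and were updated with a RefSeq gene table of assembly GRCm38.p6, from which no coordinates were used. Of the pairs of array name and gene, 12559 matched as a current symbol, 3905 as an older symbol and 637 not at all. For 16 gene lists fixed before the data were examined, the median of each gene's highest set mean was compared with 10000 random lists of the same size drawn from genes of the same quintile of probe number, among genes with at least 3 probes. These random lists were not matched on array, although 5000 called probes lay on array 1 and 397 on array 2 with all spots. A list among the top or bottom 2.5% was read as standing apart, a bound that was not part of the design. Percentiles of a list are those of its median and not of its number of called members, unless a count is named. Named genes are the 15 called genes with the highest set mean, the 4 highest of each list, and 20 fixed genes, with their values whether called or not, except some genes that are not reported here. Motif shares of called probes were compared with uncalled probes of the same GC decile, with 95% Wilson intervals.

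Alternatives chosen at the outset changed the signal (log10 ratio column, normexp with an offset of 50, signals before dye normalization, subtraction of a lowess trend on intensity fitted to binned medians), left out probes with dim input or with any outlier or saturation mark, or changed the set probability (0.0001 and 0.01), the single-probe conditions, the neighbour distance (500 bp), the scale and the minimum set mean (1). After the data were seen, random lists matched also on GC content were added for the gene lists, with all and with measured spots, and 4 alternatives were added for the calls: spots measured in both channels, that is without surrogates, which left 278799 probes before the non-uniform spots were removed; subtraction of the median log ratio per GC bin of 2%; both together; and measured spots without probes that hold CGGCGGC. The position of called probes relative to transcription starts was not computed, because an annotation in the build of the arrays was not used here.

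The caller was tested on simulated data at the 474380 real probe positions, with 50 planted regions per height. Normal scatter of the arrays' own scale was drawn independently for each probe, without surrogates or a GC trend. The caller recovered 6% of regions with a log2 height of 1, 14% at 1.5, 44% at 2 and 98% at 3. Of its 129 calls, 48 were not planted. Of 200 simulated gene lists without a shift, 5 reached the top 2.5%, and all 200 with a shift of 0.5 (log2) did, on 16831 genes. For 3000 probes picked by GC content alone, the Tcf/Lef core share stood at 0.91 of that of matched probes and 0.58 of that of unmatched ones. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1 for normexp.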

Results

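The binding of Tcf3 to promoter DNA was measured in E14 cells, a mouse embryonic stem cell line, by chromatin immunoprecipitation followed by hybridisation to promoter arrays. Tcf3, now named Tcf7l1, is a DNA-binding factor of the Tcf/Lef family through which the Wnt pathway acts on its target genes. Amplified DNA from the immunoprecipitate was labelled with Cy5 and amplified input DNA with Cy3, and both were hybridised together to each of 2 arrays. Whether both arrays received the same immunoprecipitate is not given in the sources used here. Array 1 held 237195 probes, mostly on chromosomes 1 to 8, and array 2 held 237185 probes, mostly on chromosomes 9 to 19 and X, with 0 probes in common. Both arrays are therefore parts of one promoter set, so that each gene was measured without a replicate and without a control immunoprecipitation, and the number of arrays limits the precision. Neighbouring probes lay a median of 183 bp apart on array 1 and 182 bp apart on array 2. The input gave signals well above background at 97.8% of the probes of array 1 and 92.0% of those of array 2, and the immunoprecipitate at 69.1% and 48.1%. In 30.7% of the probes of array 1 and 51.7% of those of array 2, the Cy5 value was a surrogate that stood in for a signal not above background. Values below are set means, the mean log2 ratio of Cy5 over Cy3 of a probe and its nearest neighbours, each with the SD over the probes of the set. That SD describes scatter along the DNA and not error between experiments. The genome build of the array coordinates is not given in the sources used here.

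Which promoters Tcf3 occupied was the question of the experiment. The gene of Tcf3 itself, Tcf7l1 (Tcf3 in the array annotation), had a set mean of 2.46 ± 0.83 (SD, 3 probes; chromosome 6, 72805248 to 72805696), a 5.49-fold excess of immunoprecipitate over input. Axin2, a negative regulator and known target of the Wnt pathway, reached 2.43 ± 0.27 (SD, 3 probes; chromosome 11, 109029832 to 109030240), and the Tcf/Lef family member Lef1 reached 2.10 ± 2.02, carried by 1 probe at 4.37. That set of Lef1 was centred on a neighbour at 1.41, which was not called itself. The probe at 4.37 was the only called probe of Lef1. Sox2, a transcription factor of the pluripotency network, reached 2.22 ± 0.57 (chromosome 3, 34453662 to 34453995). All 4 were called as bound, with all spots and with only the spots measured in both channels. Among developmental regulators, the eye and neural gene Pax6 (2.60 ± 0.48; chromosome 2, 105528286 to 105528608) and Lefty2, an inhibitor of Nodal signalling (2.51 ± 0.39; chromosome 1, 180868337 to 180868696), were called too. Pou5f1, the gene of Oct4, had a 2.83-fold excess that was not called with all spots, and was called with measured spots at a set mean of 1.68. Cdx2, a trophectoderm regulator, was not called with all spots (1.74) and was called with measured spots (1.78). It was not called with the GC trend subtracted from these (1.64), and its sets held 2 probes. Ccnd1 was called at 1.59 ± 1.00, and its set mean was 0.89, not called, when the trend of the log ratio with GC content was subtracted from the measured spots. Gata4 (1.33, from 3 surrogate spots), Gata6 (1.12), Foxa2 (1.36), Lefty1 (0.63), Dkk1 (0.89, with 1 surrogate spot) and Myc (0.70, with 2) were not called with all spots, with measured spots or with the GC trend subtracted from these. Of them, Foxa2, Gata6 and Dkk1 were called with normexp background correction and with the intensity trend subtracted, settings that called 8416 and 7424 genes. Sox17 (1.60, with 2 surrogate spots) and Zfp42 (1.15) were called with neither all nor measured spots. They were called at 2.14 (SD 1.68, 2 probes) and 1.40 with the GC trend subtracted from measured spots. Nanog, T and Sp5 are not analysed here.

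**Figure D1:**
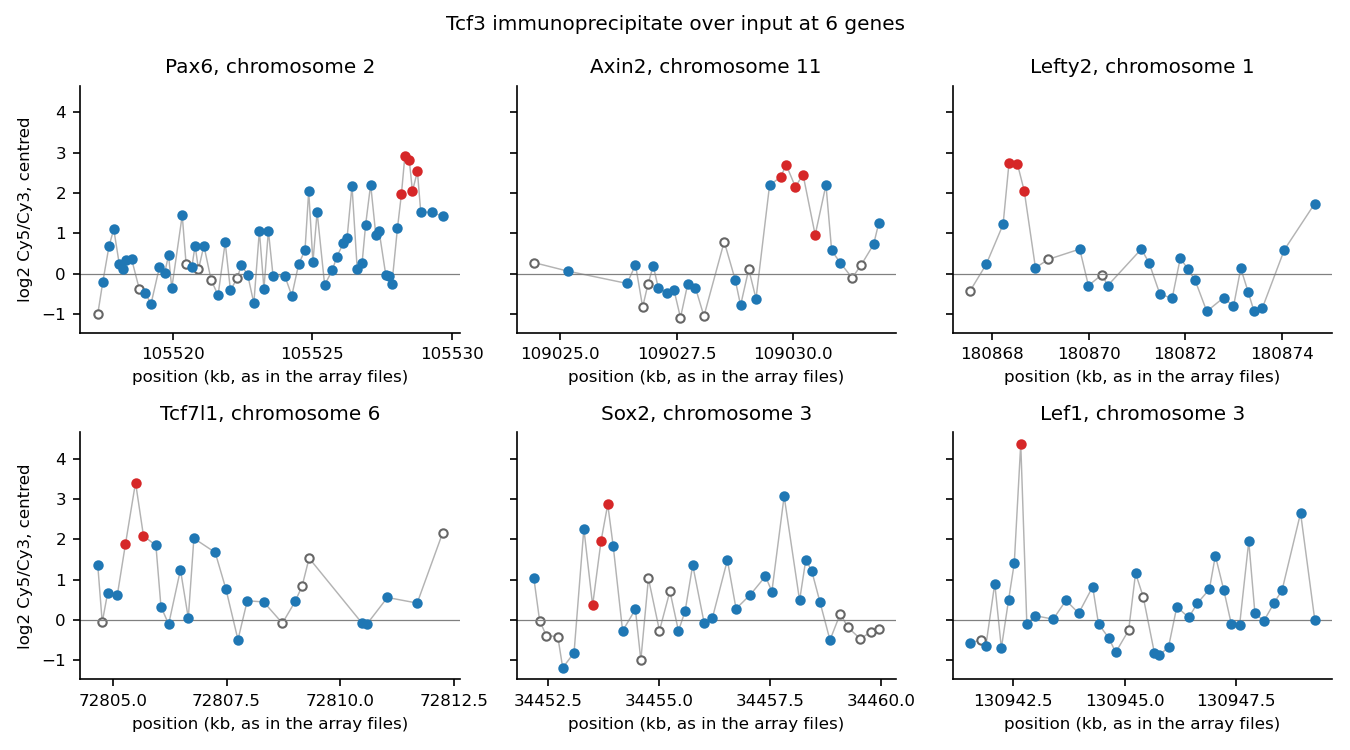
Log2 ratio of Cy5 (Tcf3 immunoprecipitate) over Cy3 (input), centred on the array median, against position in kb for the probes annotated to 6 genes. Red points are called centre probes, blue points other probes measured in both channels, and open points probes with a surrogate value. Axin2 shows neighbouring probes raised together, whereas the Lef1 call rests on 1 probe at 4.37.

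The highest set means among called genes were those of Grsf1, which encodes an RNA-binding protein, at 4.12 ± 0.73 (SD, 3 probes; chromosome 5, 88619577 to 88619914), and of the forkhead gene Foxe1, at 3.73 ± 0.35 (chromosome 4, 46358662 to 46359063). Mllt6 (3.30 ± 0.58), Tfe3 (Tcfe3 in the array annotation, 3.23 ± 0.58), Foxe3 (3.21 ± 0.91), Pard3 (3.17 ± 1.71), Nrxn2 (3.15 ± 0.22) and Rbbp7 (3.15 ± 0.41) followed. The sets of Tfe3 and Rbbp7 held only 2 probes each. B430319F04Rik (3.10), the neighbours Hs2st1 and Selenof (Sep15) that share 1 set of probes (3.08), Rif1 (3.07 ± 0.41) and Larp1b (1700108L22Rik, 3.06) completed the genes with measured spots among the 15 highest. BC043934 (3.43) and Clec2g (3.35) rested on sets of 2 surrogate spots each and fell to 0.64 and 0.34 with measured spots, where neither was called. The other 13 stayed called with measured spots and also with the GC trend subtracted, although Foxe1, whose set had a mean GC content of 69.6%, then stood at 2.48, Foxe3 (70.4%) at 1.90, Pard3 (73.3%) at 1.76, B430319F04Rik (68.9%) at 1.90, Hs2st1 and Selenof (72.6%) at 1.80 and Larp1b (71.9%) at 1.72. Sets of Foxe3 and Nrxn2 held 1 and 2 probes with the sequence CGGCGGC.

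In all, 2613 regions that named 2191 of 17039 genes (12.9%) were called, 2312 on array 1 and 301 on array 2. Of the 5397 called probes, 2849 (52.8%) had a surrogate Cy5 value, and the median GC content of called probes was 35%. With only measured spots, 2269 regions were called, 1380 on array 1 and 889 on array 2, which named 2232 genes. Their called probes had a median GC content of 62.2%. Both sets shared 1316 genes, and 761 of these were also called when the GC trend was subtracted from the measured spots. The same rule applied to input over immunoprecipitate gave 1 region, made of 44 probes of the mitochondrial genome, with all spots. Its scale of no enrichment came from the values above the median, enriched probes included. This count therefore does not measure how many calls scatter gave. Nor do the 48 calls on simulated data that were not planted, because that scatter was independent between probes, without surrogates or a GC trend. The 47 mitochondrial probes had a median log2 ratio of -2.97, all of them below 0. No test between samples exists for these calls, and the arrays differ in brightness as well as in the chromosomes they carry. Random lists used below were not matched on array, so that the array a list's genes lie on can move its count and percentile. On chromosome 9, which both arrays carry in different parts, 205 of 4344 probes of array 1 (4.72%) and 29 of 23142 of array 2 (0.13%) were called with all spots. With measured spots these were 34 of 2610 (1.30%) and 106 of 11189 (0.95%), and with the GC trend subtracted from these 53 (2.03%) and 55 (0.49%).

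**Figure D2:**
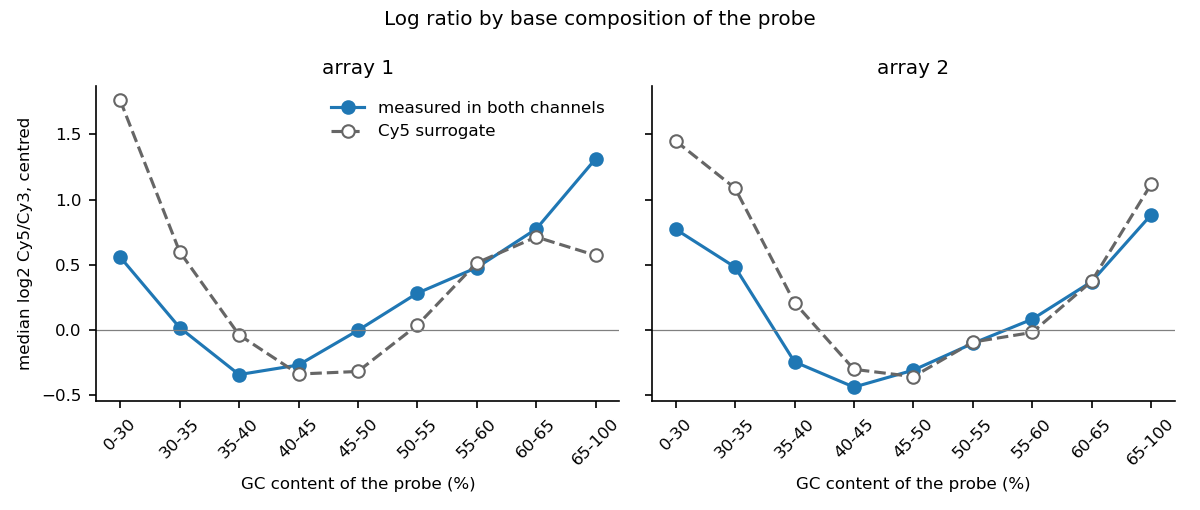
Median log2 ratio of Cy5 over Cy3, centred on the array median, by GC content of the probe in percent, for array 1 (left) and array 2 (right). Filled points are spots measured in both channels and open points spots with a surrogate Cy5 value. On array 1, surrogate spots under 30% GC had a median of 1.76 against 0.56 for measured spots.

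Genes of the pluripotency network were called more often than random lists. Of 33 list members on the arrays, 13 were called with all spots against a mean of 4.98 in random lists, and 22 with measured spots against 6.11. The median set mean of the list, 1.70, lay above all 10000 random lists of genes with as many probes, as did that of the olfactory receptors. With the median over all probes of a gene in place of the highest set mean, the list lay at percentile 97.97, below the ectoderm and neural list at 98.4 and the olfactory receptors at 100. Rif1 (3.07 ± 0.41), the homeobox gene Gbx2 (2.96 ± 1.22; chromosome 1, 89840830 to 89841206), the Krüppel-like factor gene Klf2 (2.83 ± 1.09; chromosome 8, 70838916 to 70839276) and the corepressor gene Trim28 (2.69 ± 0.50; chromosome 7, 11600924 to 11601413, with 1 surrogate spot) led the list. Zbtb45, which is not in the list, had the same set mean as Trim28 (2.69), also with measured spots and with the GC trend subtracted. Called members outside the leading group included Sox2 and Fgf4, the latter a growth factor of embryonic stem cells, at 2.18 ± 0.14. With the GC trend subtracted from measured spots, 21 of the 33 were called.

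Signalling genes were called in part. In the Wnt pathway list, 8 of 38 members were called with all spots, among them Tcf7l1, Axin2, Lef1 and the corepressor gene Tle1 (1.99 ± 1.06), and the list median lay at percentile 68.8 of random lists. With measured spots 14 of 38 were called against 7.01 in random lists, with the list median at percentile 99.7. After the GC trend was subtracted from these, 14 of 38 were called against 6.31, with the list median at percentile 100. The Nodal and BMP list had 6 of 22 members called with all spots and 10 of 22 with measured spots, against 4.12 in random lists. Its median lay at percentile 97.0 with all spots and 99.9 with measured spots, and at 88.8 when the GC trend was subtracted from the latter, where 8 of 22 were called against 3.72. Lefty2, Skil (2.13 ± 0.99, and 1.15 with the GC trend subtracted from measured spots) and Id1 (1.97 ± 0.40) were called, and Nodal itself (1.99 ± 0.64) was called with measured spots. Of the Fgf list, 5 of 15 members were called with all and with measured spots, led by Fgfr2 (2.71 ± 0.38) and Fgf4, and its median lay at percentiles 52.5 and 82.5. After the GC trend was subtracted from measured spots, the Fgf list had 4 of 15 called and its median at percentile 76. Spry2 (1.83) and Spry1 (1.79, with 1 CGGCGGC probe), inhibitors of Fgf signalling, lost their calls when the GC trend was subtracted from measured spots.

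Among lineage regulators, mesoderm genes were called in 5 of 21 members with all spots and 8 of 21 with measured spots, against 3.87 in random lists, with the list median at percentiles 94.7 and 98.8. Of the same list 11 of 21 were called against 3.52 with the GC trend subtracted from measured spots, with the list median at percentile 100. Gata2 (2.35 ± 2.08), Mesp1 (2.25 ± 0.27), Cdx1 (2.20 ± 0.65) and Evx1 (2.13 ± 0.42) led it. The ectoderm and neural list had 5 of 28 members called with all spots and 9 of 28 with measured spots, counts at percentiles 60.95 and 94.3. Its median lay at percentiles 71.5 and 99.2. After the GC trend was subtracted from measured spots, 12 of 28 were called, with the list median at percentile 99.9. The list was led by Pax6, Lmx1b (2.32 ± 0.20), Dlx5 (2.14 ± 1.18, with 1 surrogate spot) and the uncalled Msx1 (1.89 ± 1.19). Of the Hox clusters, 5 of 33 genes were called with all spots and 10 of 33 with measured spots, with the list median at percentiles 39.5 and 99.4. After the GC trend was subtracted from measured spots, 11 of 33 were called, with the list median at percentile 99.98. Hoxd13 (2.54 ± 1.73), Hoxd9 (2.48 ± 1.07), Hoxd10 (2.27 ± 1.62) and Hoxa13 (2.11 ± 0.69) were the highest, of which Hoxd10, with 1 surrogate spot, was not called with measured spots, and Hoxd9 and Hoxa13 had 1 CGGCGGC probe each. Hoxa13 lost its call when the GC trend was subtracted from measured spots, and Hoxd9 then stood at 1.54. Of the endoderm list, 1 of 15 genes was called with all and with measured spots, Foxa1 at 1.85 ± 0.53, which was not called with the GC trend subtracted from measured spots, with Dab2 at 1.52 from 3 surrogate spots. After that subtraction 2 of 15 were called, Sox17 at 2.14 and Afp at 1.47. The list median lay at percentile 22.9 with all spots, 65.1 with measured spots and 86.2 with the GC trend subtracted from these. Of the trophectoderm list, 1 of 11 members was called with all spots, Fgfr2, and 2 of 11 with measured spots. Cdx2, Ascl2 (1.54, and 0.66 with the GC trend subtracted from measured spots) and Tfap2c (1.36) were not called with all spots, and the list lay at percentiles 22.9, 58.0 and 84.6 in the same settings.

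Other lists included genes not tied to development. Cell cycle genes were called in 4 of 19 members with all spots, with the list median at percentile 83.3. Measured spots gave 6 of 19 called against 2.96 in random lists, a count at percentile 96.06, with the list median at percentile 98.8. With the GC trend subtracted from these, 5 of 19 were called, with the list median at percentile 56.95. The list was led by Mycn (2.65 ± 0.46), E2f1 (2.31 ± 0.89), Cdkn2a (2.14 ± 0.54, with 1 CGGCGGC probe) and Trp53 (1.76 ± 0.70), the last not called with all spots and called with measured spots. E2f1 stood at 1.37 and Cdkn2a at 1.36 with the GC trend subtracted from measured spots. Chromatin and corepressor genes were called in 4 of 25 members with all spots, with the list median at percentile 36.9. Measured spots gave 7 of 25 called against 4.11, with the list median at percentile 98.05. With the GC trend subtracted, 7 of 25 were called, with the list median at percentile 49.65. The list had Dnmt3b (2.58 ± 1.22), Ctbp2 (2.36 ± 1.42), Jarid2 (2.08 ± 1.02) and Tle1 at the top, of which Jarid2 lost its call with the GC trend subtracted from measured spots, where Dnmt3b stood at 1.61. Ribosomal protein genes lay low, with 6 of 92 called against 10.6 in random lists and a list median at percentile 0.28, although Rpl7 (2.65 ± 0.54) and Rpl28 (2.18 ± 1.43) were called, at 1.36 and 1.31 with the GC trend subtracted from measured spots. Against random lists matched also on GC content the list lay at percentile 4.38, no longer in the bottom 2.5%, with 6 called against 8.56. With measured spots 4 of 92 were called against 12.9, with the list median at percentile 0.78. After the GC trend was subtracted from these, 7 were called against 12.4, with the list median at percentile 1.53. Their percentile was 66.05 with the normexp background correction. Rps27l (2.04 ± 0.92) was called from a set with 2 surrogate spots and was not called with measured spots. Of the housekeeping list 1 of 14 members was called with all spots, and the list lay at percentile 37.1. With measured spots 5 of 14 were called against 2.16 in random lists, and the median lay at percentile 51.15. With the GC trend subtracted from these, 2 of 14 were called against 2.04, with the list median at percentile 4.89. Hprt (1.90, with 1 surrogate spot), Ywhaz (1.56) and Eno1 (a 2.79-fold excess) were called with measured spots and not with all spots, and of these Hprt (1.37) and Ywhaz (0.97) were not called with the GC trend subtracted from measured spots. Terminal tissue genes had a median at percentile 0.49, and the 3 of 18 that were called, Fgb (2.15), Hbb-b1 (2.05) and Gcg (1.86), rested on 2 to 3 surrogate spots and were not called with measured spots, nor was Ckm (1.70). With measured spots 0 of 17 were called. With the GC trend subtracted from these, Fgb was called at 1.23 and the list lay at percentile 34.98. In the feeder fibroblast list, which holds markers of cells that can accompany stem cell cultures, 1 of 14 was called, Postn (1.99 ± 1.01, with 1 surrogate spot), and the list lay at percentile 85.4, with measured spots at 33.0 and with the GC trend subtracted from these at 94.6, with Col3a1 at 1.87 from 3 surrogate spots, Twist1 at 1.55 and Prrx1 at 1.52.

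Olfactory receptor genes, which are silent in most tissues, were called in 303 of 851 members with all spots, against 99.6 in random lists, and their median lay above all of these. Random lists matched also on GC content had 186 called and a mean median of 1.47 against 1.55, with the olfactory list still at percentile 100. With measured spots 62 of 568 were called against 43.9, and with the GC trend subtracted from these 130 against 57.1. Such spots were kept because their Cy5 was above background, which itself favours high ratios. After normexp background correction 133 of 851 were called against 384 in random lists, so that the list moved from above to below all random lists. Olfr47 (2.91), Olfr1406 (2.77) and Olfr1299 (2.71) had surrogate spots in their sets, of which Olfr47 and Olfr1406 were not called with measured spots. The set of Olfr645 (2.67 ± 0.96) had none. Each of these sets held 2 probes.

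**Figure D3:**
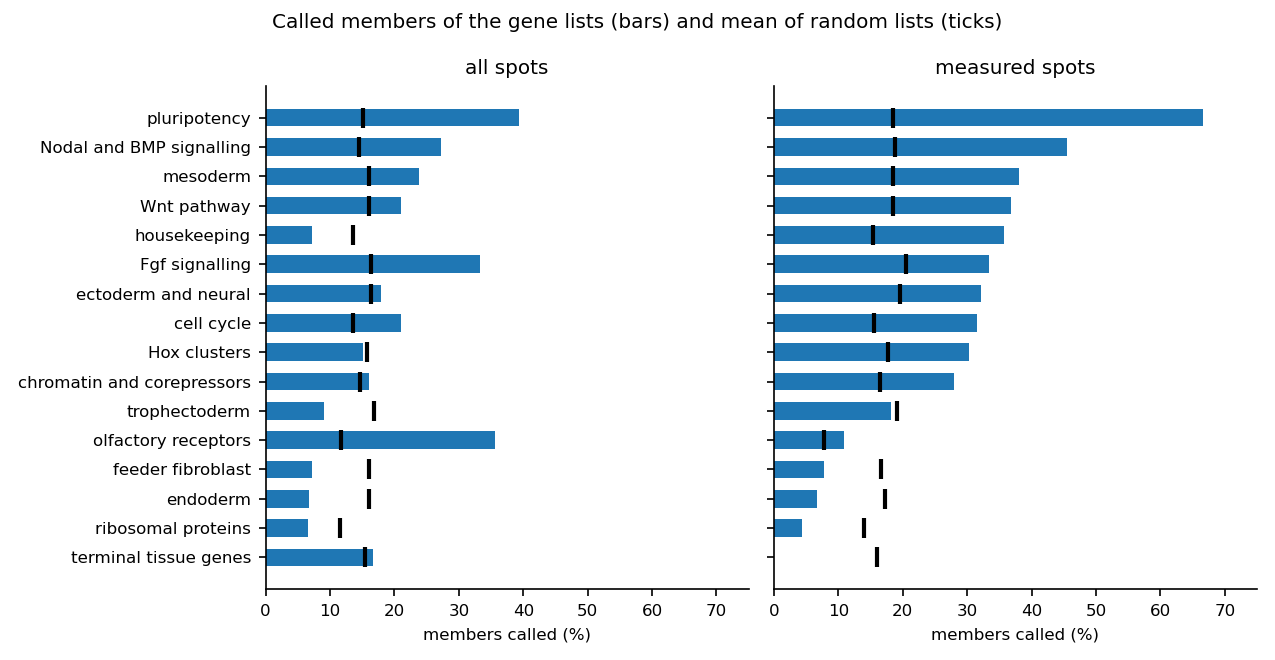
Share of the tested members of each gene list that were called, in percent, with all spots (left) and with spots measured in both channels (right). Bars are the observed shares and black ticks the mean share in 10000 random lists. The pluripotency list reached 39.4% and 66.7%, and the olfactory receptors went from 35.6% to 10.9%.

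The sequence of the probes was searched for the Tcf/Lef core WWCAAAG (W is A or T). With all spots, 316 of 5397 called probes (5.86%, 95% Wilson interval 5.26% to 6.51%) held it, 1.02 times the share of uncalled probes of the same GC content. With measured spots and the GC trend subtracted, 238 of 3572 called probes (6.66%, 5.89% to 7.53%) held it against 5.49%, a ratio of 1.21 (1.07 to 1.37), while the reversed control GAAACWW stood at 1.02 (0.88 to 1.18). The Oct site ATGCAAAT was found in 32 of these probes (0.90%) against 0.36%, a ratio of 2.47 (1.75 to 3.48), and the Sox site CATTGTT at a ratio of 1.25 (0.94 to 1.65). With all spots the Oct site stood at 1.20 (0.83 to 1.73), the Sox site at 0.98 (0.77 to 1.25) and the control at 1.00 (0.90 to 1.12). With measured spots alone the Tcf/Lef core stood at 1.52 (1.29 to 1.79), the Oct site at 2.94 (1.84 to 4.70), the Sox site at 1.64 (1.13 to 2.36) and the control at 1.32 (1.08 to 1.60). These intervals cover counting error only.

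Repeated control spots gave the only measure of technical scatter. Among control probes with at least 10 measured spots, the median SD of the log2 ratio was 0.12 on array 1 (17 probes) and 0.13 on array 2 (11 probes). Mean log2 ratios of the 11 control probes found on both arrays correlated at Pearson r 0.98 and Spearman rho 0.98, across probes that are not independent replicates. In the series value table, all 243496 values of array 1 and all 243486 of array 2 equalled the error of the log10 ratio in the scanner files. Their medians were 0.210 and 0.353, their slopes on the log10 ratio -0.0719 and 0.0312, and their correlations with it -0.0864 and 0.0287 (Pearson, across spots).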

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

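The tests of explanations were chosen after the calls had been seen. What each would show was written before the result for the 2 sums over olfactory receptor probes (the sum over called probes was added once the sum over all had been seen), the match on the number of CpG and the neighbours of CGGCGGC probes, and after it for the others.

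With measured spots, 38 called regions carried no gene name in the array annotation and entered none of the gene comparisons. The highest lay on chromosome 17 (64000347 to 64001300, set mean 2.98, 4 called probes), followed by regions on chromosome 5 (16861075 to 16861285, 2.62) and chromosome 2 (118642509 to 118642876, 2.61).

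The many calls at olfactory receptor genes, 303 of 851 members with all spots, were set against surrogate Cy5 values in 3 tests, of which 0 decided the question. Summed background-subtracted Cy5 over Cy3 of all 19731 probes of these genes, counted once per gene (20233 pairs of probe and gene), lay -0.18 (log2; 95% bootstrap interval over genes -0.25 to -0.10) from that of other probes, and 0.098 (-0.0073 to 0.20) from probes of the same GC content, but the 1476 called probes at their set means would have moved this sum by 0.066. Over the called probes, of which 86.4% had a surrogate Cy5 value, the sum lay 1.35 (1.16 to 1.52) above that of other probes, past the 1 (log2) written beforehand as arguing against surrogates. That bound was wrong, because low Cy3 helps a probe to be called: the same Cy3 with the mean Cy5 of uncalled surrogate spots gave 1.62 (1.47 to 1.75), a reference added after the 1.35 had been seen. Without surrogates, 62 of 568 members were called against 43.9 in random lists, and 130 against 57.1 with the GC trend subtracted. Their spots were kept because their Cy5 was above background, a selection that itself favours high ratios. Members called without surrogates do not bear on the other calls. Over all genes, 72 of 2849 called probes with a Cy5 surrogate were also called before dye normalization and 49 with normexp. Of 2498 called probes measured in both channels, these were 1992 and 2052. Such counts go with surrogate values as the cause. Olfactory receptor probes were not counted apart, but 1276 of the 2849 were theirs. At most 72 of these 1276 were therefore also called before dye normalization. This bound goes with surrogate values for most of the 1276, short of a test of them alone. No biological explanation was tested.

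For the high set means at pluripotency genes, surrogate values and base composition are argued against as the whole cause: 22 of 33 members were called without surrogates, above the 6.11 of random lists, and 21 with the GC trend subtracted as well, against 5.52. Without CGGCGGC probes 21 members were called too. An unspecific pull-down of the promoters of highly expressed genes would raise the ribosomal protein genes, whose percentile was at most 66.05 over the settings run, and the housekeeping genes, of which 5 of 14 were called against 2.16 with measured spots and 2 against 2.04 with the GC trend subtracted. The median of the housekeeping list reached percentile 95.71 with normexp, short of the top 2.5%, so that these lists leave such a pull-down open. Binding by Tcf3 and an affinity of the antibody for another protein at these promoters stay open too, since no control immunoprecipitation is analysed here.

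Called regions of measured spots were rich in CGGCGGC, which 169 of 2269 top probes (7.45%) held. This was 3.86 times (3.33 to 4.45) the share in probes of the same GC content, the comparison by which the sequence was picked as rank 1 of 2033 and which therefore tests nothing. Against probes of the same GC content and number of CpG the ratio was 2.68 (2.32 to 3.09). In this match the probes of highest GC content were pooled, and so were those with the most CpG. The ratio argues against these 2 properties as the whole cause, apart from differences within the pooled probes, although the sequence was picked on the same probes. In 234 pairs, probes with CGGCGGC lay 0.94 (0.82 to 1.05, log2) above matched probes, whereas their neighbours within 250 bp of under 50% GC lay 0.016 (-0.067 to 0.10) above those of matched probes, 0.017 (-0.071 to 0.11) of the excess. Fragments longer than that distance would have raised both, so that hybridisation of single probes is a candidate explanation for these probes, not tested on neighbours of higher GC content.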

How the results depend on the processing

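Alternatives with measured spots, GC matching, the GC trend or CGGCGGC probes left out were chosen after seeing the data. The 2613 called regions became 1368 with the log10 ratio column, 9707 with normexp, 8925 with the intensity trend subtracted, 1685 at a set probability of 0.0001, 3947 on set probability alone and 617 with the SD of all probes as scale, and stayed within 1.5 times in the other settings. The 2191 called genes became 1352, 8416, 7424, 1398 and 605 in these settings apart from set probability alone, and 3598 with signals before dye normalization. The mirror count of 1 region became 11571 with the log10 ratio column, 130 before dye normalization, 580 with the intensity trend subtracted, 2 on set probability alone, 30 with the GC trend subtracted and 2 with measured spots and the GC trend. The 2 gene lists in the top 2.5% of random lists became 7 with normexp, 6 with the intensity trend subtracted, 4 without matching, 4 with matching on GC, 9 with measured spots, 6 with the GC trend subtracted from these, 8 with these and GC matching, and 9 without CGGCGGC probes. The pluripotency list stayed past the bound in every alternative that moved the list values, its lowest percentile being 98.0 with the median over all probes, and the olfactory receptors turned to percentile 0 with normexp and with the intensity trend subtracted. The ratio of the Tcf/Lef core, 1.02 with all spots, had an interval above 1 with the intensity trend subtracted (1.14), the GC trend subtracted (1.14), measured spots (1.52) and both of the latter (1.21). At a set probability of 0.0001 the core stood at 0.93 (0.80 to 1.07), below the reversed control at 1.09 (0.95 to 1.25). Without matching the core stood at 1.03 (0.92 to 1.14). Among the measured probes called with all spots it stood at 1.17 (0.96 to 1.42). Of 62 named genes called with all spots, 53 stayed called with measured spots and 48 with the GC trend subtracted as well. The cause of these changes was not tested beyond the tests described for surrogate values and probe sequence. A minimum set mean of 1 and the further outlier marks changed no call, and so say nothing about stability. Not run were the series value table, which holds errors, leaving out each array, and the position relative to transcription starts. How far the gene lists and motif shares rest on array 1, with 5000 called probes against 397 on array 2, is therefore not known. Signal over background limits the Cy5 channel, where 41.2% of all probes had a surrogate.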

Other observations

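Gene families and 7-base sequences were chosen after the data were seen. Counts of called genes per family, grouped by name, stand beside the number that the rate of all genes gives, and differences from it were not tested. Of 16 Sox genes, 8 were called with measured spots, against 2.19, and 7 with the GC trend subtracted. Sox2, Sox3, Sox4 and Sox21 were called in both settings, and of these 4 Sox2 was called with all spots. Of 9 Frizzled genes, which encode Wnt receptors, 6 and 4 were called against 1.23 and 1.21. Of 12 Nkx homeobox genes, 5 and 6 were called against 1.64 and 1.61, and of 5 Zic genes 4 and 3 against 0.68 and 0.67, but 0 with all spots against 0.65. Forkhead genes were called in 16 of 40 with measured spots and in 9 of 40 with the GC trend subtracted, against 5.48 and 5.36. Of 43 keratin genes, 0 with measured spots and 1 with the GC trend subtracted were called, against 5.89 and 5.76. The families named so far are only part of those counted, and others lay near the rate. Lhx genes had 0 of 6 called in both settings. Zinc finger Zfp genes had 32 of 232 called with measured spots against 31.8, and solute carriers 47 of 338 against 46.3. Pax genes had 1 of 9 called with measured spots against 1.23, and 5 with the GC trend subtracted against 1.21. These rates were not matched on probe number.

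Among 7-base sequences in the top probes of called regions, CGGCGGC ranked 1 with all spots, with measured spots and with the GC trend subtracted. The sequence AACACAC ranked 3 in the last of these, in 108 top probes against 33.6 expected from probes of the same GC content. The Oct-like ATTTGCA ranked 51 there, in 48 top probes against 22.8. Of the Tcf/Lef variants, AACAAAG ranked 55 with measured spots, in 40 against 15.4, ATCAAAG ranked 453, and TACAAAG and TTCAAAG, read as CTTTGTA and CTTTGAA, ranked 671 and 673. With all spots TACAAAG ranked 249, in 42 against 28.1, AACAAAG 1065, TTCAAAG 1656 and ATCAAAG 3005 of 3278. With the GC trend subtracted from measured spots AACAAAG ranked 187, TTCAAAG 439, TACAAAG 1278 and ATCAAAG 1414.

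Probes of the X chromosome had a median log2 ratio of 0.75 with all spots (17339 probes), where 67.4% had a surrogate Cy5 value, and of 0.38 with measured spots and the GC trend subtracted. The latter rests on 5607 probes, kept because their Cy5 was above background, a selection that itself favours high ratios. No other nuclear chromosome exceeded 0.074 in that setting. The mitochondrial probes stood at -3.04 there. With all spots the 204 probes of the Y chromosome had a median of 0.69, near that of the X chromosome, and 68.6% had a surrogate Cy5 value.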
